A study of Homo sapiens with 12 samples.

How the data were processed

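Gene expression was measured on 12 Illumina bead arrays, 4 for each of 3 groups of one ovarian cancer cell line: untransfected cells, cells given a scrambled siRNA (control siRNA) and cells given an siRNA against EZH2. The sample names call the line SKOV3ip and the source labels call it SKOV3. The labels name 2 array types, HumanHT-12 for the series and Human-6 version 3 for the samples; the files hold 48803 probes, the number that the labels give for the latter. The labels do not say whether the 4 arrays of a group come from separate cultures, so p-values measure only the spread between arrays, which may be technical.

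The deposited raw table holds 1 intensity per probe and array, exported with BeadStudio 3.2 per the labels. Its background and summary settings are not given in the sources used here. The second deposited table holds log2 values; taking log2 of the raw table and then quantile-normalising it, with no background correction, matched each of its values to within 0.00005. The raw table was used for the main results and the log2 table for an alternative, and 0 columns of sample values were left unused.

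Raw intensities were background-corrected with normexp (offset 50) and quantile-normalised in limma 3.58.1 under R 4.3.3, and all levels below are on the resulting log2 scale. The added offset shrinks the log2 fold changes of probes with signal near background. The filter fixed before the data were examined used detection p-values, which these files do not carry. In their place, each array's background was taken as the most frequent signal value with the spread of the values below it mirrored above it. A probe was tested if it lay above that background at p under 0.01 on at least 4 of the 12 arrays, whatever their group; 17297 probes were tested and 31506 were not. The reference table gave 1 gene symbol for 28098 probes, several for 13 and none for 20692; 10967 genes had at least 1 tested probe, and the brightest tested probe stands for a gene.

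All 12 arrays were fitted in 1 linear model with 3 groups (lmFit and eBayes of limma), and p-values were adjusted over all tested probes by the Benjamini-Hochberg method. A probe with an adjusted p under 0.05 was called. Single genes of interest also had an exact two-sided permutation test of the group means, whose smallest possible p with 4 arrays against 4 is 0.0286. The 3 comparisons were EZH2 siRNA against control siRNA, control siRNA against untransfected cells, and EZH2 siRNA against untransfected cells. The first and last share the EZH2 siRNA arrays, and the first and second share the control arrays.

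The 25 gene lists were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 25 lists of a comparison. Genes named in the text follow a rule fixed at the same time: EZH2, EZH1, SUZ12, EED and VASH1; the 6 largest rises and the 6 largest falls among called genes whose arrays did not overlap between groups; and up to 2 called genes of each list with the largest change (in the comparisons with untransfected cells, of each list called by camera). Genes named outside the rule are marked as chosen after their values were seen.

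The pipeline was tested on simulated data with the spread of these arrays. Over 10 runs with 200 changed probes, 39.9% of log2 changes of 0.5 were called, 94.3% of changes of 1 and 100% of changes of 2, and 4.88% of calls were false. A list shifted by 0.4 was found in 5 of 5 runs, and 0 unshifted lists were called. Probes were simulated independently of each other, so these runs do not show how often lists of correlated genes are called falsely.

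Alternatives fixed before the data were examined covered the scaling between arrays (75th percentile shift, cyclic loess), no background correction, the deposited log2 table, other filters, array weights, other variance priors, fitting 2 groups alone, the replicate number as a block, the mean over a gene's probes, stricter thresholds and leaving out each array. Another 4 alternatives were chosen after seeing the data, because the arrays differed in brightness: normexp with each array's own background and an offset of 16, array brightness as a covariate, the fit without the 3 arrays of mean raw signal under 250, and a 75th percentile shift over the probes above background on all 12 arrays. Figures were drawn with matplotlib 3.10.9.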

Results

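RNA levels were compared between untransfected SKOV3ip cells, a subline of the human ovarian cancer line SKOV3, and the same cells given a scrambled control siRNA or an siRNA against EZH2, with 4 arrays per group. EZH2 is the methyltransferase of Polycomb repressive complex 2 (PRC2), which silences genes by methylating histone H3, and the series is titled for its part in angiogenesis. Mean raw signal per array was 299 ± 106 intensity units in untransfected cells (SD, n = 4), 327 ± 41.7 with control siRNA and 240 ± 50.2 with EZH2 siRNA. The share of probes above background was 33.8% ± 4.51, 35.4% ± 1.82 and 31.2% ± 2.67 in the same order. The dimmest arrays were untransfected array 4 with a mean signal of 156.7, EZH2 siRNA array 1 with 186 and EZH2 siRNA array 4 with 210. Normalised arrays of 1 group correlated across probes at 0.975 to 0.993, and arrays of different groups at 0.958 to 0.988. The number of arrays limits the precision of every value below; the median standard error of a log2 fold change was 0.13.

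**Figure D1:**
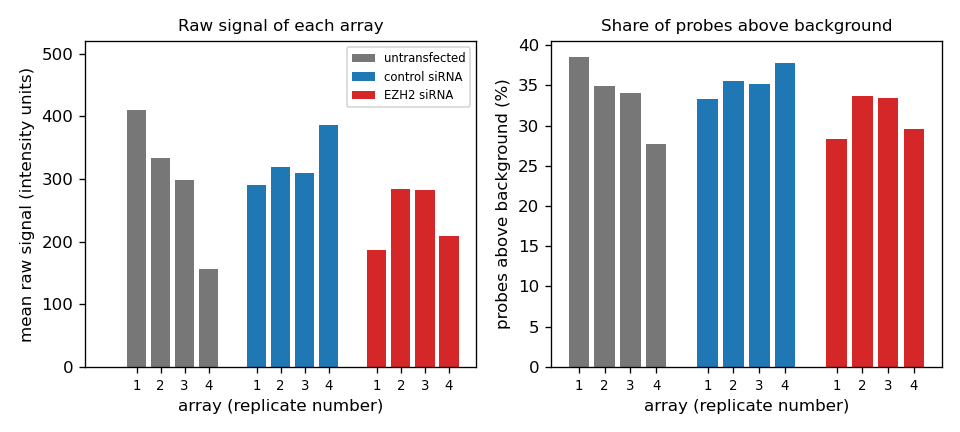
Mean raw signal (left, intensity units) and percentage of probes above background (right) of each of the 12 arrays, coloured by group. EZH2 siRNA arrays averaged 240 against 327 with control siRNA, and untransfected array 4 was the dimmest at 156.7.

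EZH2 mRNA was lower in the cells given EZH2 siRNA, and VASH1, an angiogenesis inhibitor made by endothelial cells, did not pass the test. The brightest EZH2 probe (ILMN_1708105) averaged 7.98 ± 0.26 in untransfected cells (SD, n = 4), 7.56 ± 0.17 with control siRNA and 6.68 ± 0.24 with EZH2 siRNA on the log2 scale. EZH2 was thus 1.84-fold lower with EZH2 siRNA than with control siRNA (log2 fold change −0.88, SE 0.15, 95% confidence interval −1.18 to −0.58, adjusted p = 0.0013 in limma). All 4 EZH2 siRNA arrays lay below all 4 control arrays (exact permutation p = 0.0286, the smallest possible). A second EZH2 probe (ILMN_2364529) fell by 0.67 (adjusted p = 0.0173), and the third (ILMN_1652913), above background on 2 of the 4 EZH2 siRNA arrays, had a log2 fold change of −0.53 (adjusted p = 0.0589). EZH2 was 2.48-fold lower than in untransfected cells (adjusted p = 3.37e-06). With each array's own background and an offset of 16, chosen after the data were seen, EZH2 was 2.66-fold lower than with control siRNA and 3.91-fold lower than in untransfected cells. The size of the fall thus depends on the background step. With control siRNA against untransfected cells the brightest EZH2 probe had a log2 fold change of −0.43 (adjusted p = 0.0876), the second probe fell by 0.62 (adjusted p = 0.0192) and the third had −0.42 (adjusted p = 0.126). VASH1 (ILMN_1796216) averaged 7.06 ± 0.18 in untransfected cells, 7.12 ± 0.13 with control siRNA and 7.21 ± 0.08 with EZH2 siRNA. Its log2 fold change against control siRNA was 0.09 (95% confidence interval −0.16 to 0.34, adjusted p = 0.747, exact permutation p = 0.286). Its sign turned under a 75th percentile scaling (−0.055) and with array brightness as a covariate (−0.0078). The other core PRC2 genes did not pass the test. SUZ12 had a log2 fold change of 0.11 (adjusted p = 0.812), which turned to −0.20 under the 75th percentile scaling, and EED one of −0.37 (adjusted p = 0.104). EZH1 was not well enough above background to be tested. The EZH2 call against control siRNA was lost under a scaling to the probes above background on all arrays (−0.59, adjusted p = 0.186), which moved the median of all probes to 0.24. Over all alternatives its adjusted p ranged from 0.000205 to that value.

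**Figure D2:**
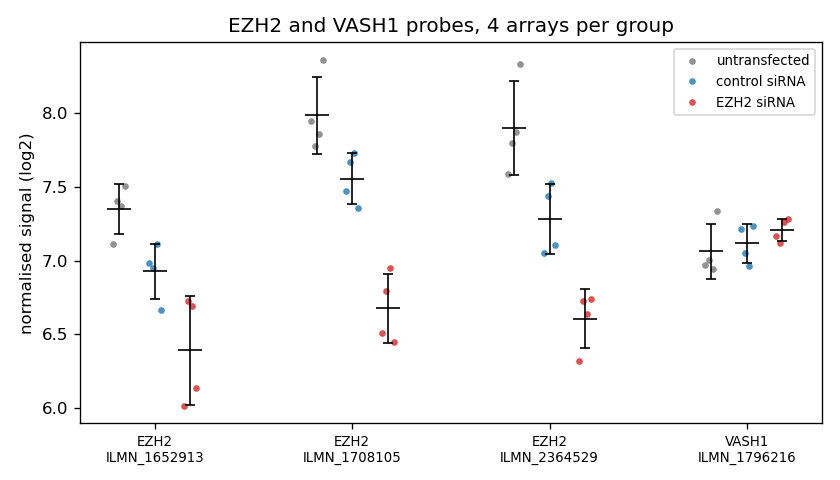
Normalised log2 signal of the 3 EZH2 probes and the VASH1 probe on each array (points) with the group mean and SD (bars, n = 4). EZH2 probe ILMN_1708105 averages 7.98, 7.56 and 6.68 in untransfected, control siRNA and EZH2 siRNA cells, and VASH1 7.06, 7.12 and 7.21; the sign of the VASH1 difference from control siRNA turned under a 75th percentile scaling and with array brightness as a covariate.

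EZH2 siRNA against control siRNA compares 2 siRNAs that were both transfected. Its changes can come from loss of EZH2 or from effects of either siRNA on other mRNAs, which were not told apart. The largest change was in PRDX6, a peroxiredoxin that reduces peroxides, which fell by 2.40 on the log2 scale (5.29-fold lower, SE 0.13, adjusted p = 8.03e-10). CBFB, the partner subunit of the RUNX transcription factors, fell by 1.57 (−1.9 to −0.91 over the alternatives). DIPK2A fell by 1.49 (−2.3 to −1.2 over the alternatives) and MTPN (myotrophin, an actin-capping regulator) fell by 1.44. NEU1, a lysosomal sialidase, fell by 1.43 and P3H2, a collagen prolyl hydroxylase, fell by 1.38. Among the largest rises, OGFR, the opioid growth factor receptor, rose by 1.40 and EMC6, a subunit of an endoplasmic reticulum insertase, by 1.21. The tropomyosin TPM4 rose by 1.17 and HABP4 by 1.17. The sulfotransferase CHST14 rose by 1.09 and the nucleolar protein NOLC1 by 1.06. All 6 of these rises were in genes that the control siRNA had lowered against untransfected cells, with log2 fold changes from −0.51 (OGFR) to −1.58 (TPM4). TPM4, HABP4, CHST14 and NOLC1 did not differ from untransfected cells by the test after EZH2 siRNA (−0.41, 0.09, −0.08 and −0.16). NEU1 had risen by 0.92 with control siRNA and lay below untransfected cells after EZH2 siRNA (−0.51, adjusted p = 0.0058). In all, 733 of 17297 probes were called, 318 higher and 415 lower with EZH2 siRNA, for 600 genes. Of the called probes, 44 differed at least 2-fold, 12 higher and 32 lower. This count depends on the background step. With each array's own background and an offset of 16, 31 of 433 called probes were at least 2-fold higher and 82 at least 2-fold lower. The arrays of the groups did not overlap for 86.9% of the called probes and for 10.9% of all tested probes, against 2.86% by chance. The EZH2 siRNA arrays were dimmer than the control arrays, and without the 3 dimmest arrays of the series 169 probes were called, of which 160 were among the 733. All 733 kept their sign, which says little because they were called from a fit that includes these same arrays. The count was 144 under a 75th percentile scaling (9 higher and 135 lower), 98 with that scaling over the probes above background on all arrays, and 278 to 1289 when 1 array was left out.

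**Figure D3:**
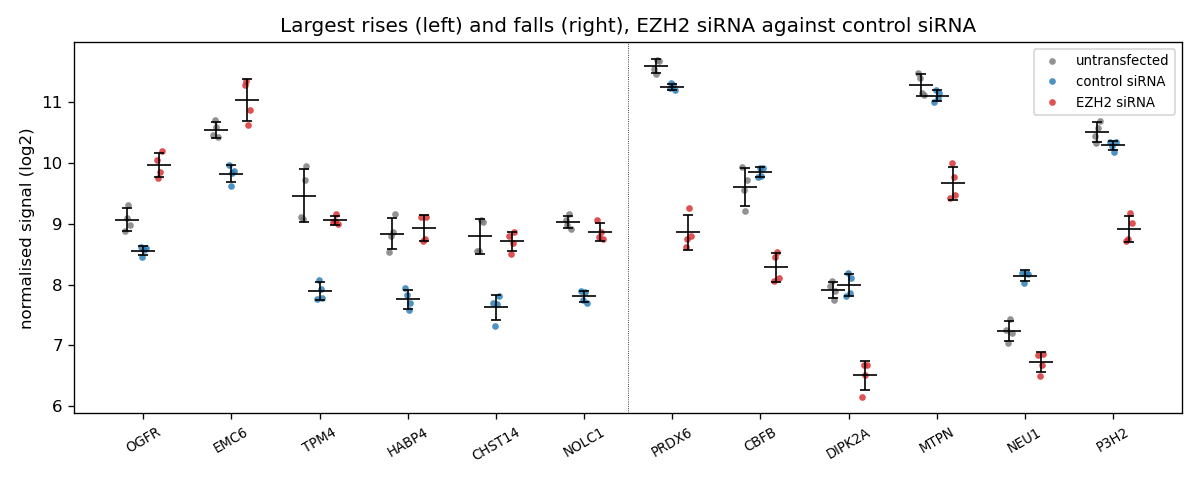
Normalised log2 signal on each array (points, with group mean and SD, n = 4) of the 6 genes with the largest rise and the 6 with the largest fall with EZH2 siRNA against control siRNA. TPM4, HABP4, CHST14 and NOLC1 are lower with control siRNA than in both other groups, whereas PRDX6 is lower with EZH2 siRNA than in both (log2 fold change −2.40 against control siRNA).

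Among the gene lists, interferon response genes rose with EZH2 siRNA beyond their level with control siRNA. Of 33 tested members, 8 rose and 0 fell (9 rose and 1 fell adjusted over the list alone). They were led by ISG15, a ubiquitin-like protein (log2 fold change 1.01), and the virus restriction factor BST2 (0.65). The list median was 0.18 (camera adjusted p = 4.25e-06, and adjusted p = 0.0427 with an estimated correlation). This was the only one of 9 lists called at the preset correlation that was called with an estimated one, and fry called 13 lists. Of 35 splits of the 8 arrays, 2 gave an interferon list median as far from 0.

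Among genes of blood vessel growth, both inhibitors and stimulators had members that fell. Of 14 tested angiogenesis inhibitors, 2 fell and 0 rose (4 and 0 adjusted over the list alone, median −0.22, camera adjusted p = 0.00331, adjusted p = 0.223 with an estimated correlation). They were thrombospondin 1, THBS1, which fell by 1.08, and the metalloprotease ADAMTS1, which fell by 0.86. Of 29 tested angiogenic factors, 4 fell and 0 rose (9 fell and 1 rose adjusted over the list alone). Adrenomedullin (ADM) fell by 1.27 and the matricellular protein CCN2 fell by 1.07. HBEGF and PLAU had the smaller changes of −0.50 and −0.44. They, COL4A1 and LAMC1 complete the counts of called genes and were named after their values were seen. The median of the angiogenic factors was −0.13 (camera adjusted p = 0.00632, adjusted p = 0.211 with an estimated correlation) and turned to 0.051 under the scaling that moved the median of all probes to 0.24. Of 25 tested genes of extracellular matrix and adhesion, 4 fell and 0 rose (6 and 0 adjusted over the list alone, median −0.27, camera adjusted p = 0.000113, adjusted p = 0.211 with an estimated correlation). They were THBS1, COL4A1, LAMC1 and the laminin chain LAMB1, which fell by 0.71. LAMB1 had risen by 0.56 with control siRNA and did not differ from untransfected cells by the test after EZH2 siRNA (−0.15). With control siRNA against untransfected cells 4 genes of this list rose (ITGA3, ITGA5, LAMB1 and LAMB3, named after their values were seen) and THBS1 fell. Of 16 TGF-beta targets, 4 fell, THBS1 and CCN2 among them, and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.0150, adjusted p = 0.306 with an estimated correlation), with a median of −0.08 that turned to 0.052 under the same scaling. THBS1, CCN2 and COL4A1 each stand on more than 1 of these lists.

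Of 23 tested genes of the integrated stress and unfolded protein response, 5 rose and 0 fell (6 and 0 adjusted over the list alone). DDIT4, an mTOR pathway inhibitor (0.98), and the mitochondrial enzyme PCK2 (0.67) were among them. PCK2 ranged from 0.27 to 0.75 over the alternatives and lost its call with the mean over its probes and under the 75th percentile scaling. The list median of 0.14 (camera adjusted p = 0.00147, adjusted p = 0.211 with an estimated correlation) turned to −0.14 under the 75th percentile scaling, which moved the median of all probes to −0.11. Of 19 NF-kB and inflammatory genes, 2 fell and 1 rose (7 fell and 1 rose adjusted over the list alone, median −0.24, camera adjusted p = 0.0258, adjusted p = 0.321 with an estimated correlation). TNFAIP3, an inhibitor of NF-kB signalling, fell by 0.64 and IER3 rose by 0.63. Of 35 genes of G2 and mitosis, 2 fell and 0 rose (2 and 0 adjusted over the list alone, median −0.16, camera adjusted p = 0.0258, adjusted p = 0.223 with an estimated correlation). Both, ANLN (−0.52) and PRC1 (−0.45), act in cytokinesis. With array brightness as a covariate the median was −0.079 and the list was not called (camera adjusted p = 0.136), nor was it without the 3 dimmest arrays. Of 12 genes of the microRNA and siRNA machinery, 2 fell and 0 rose (the same counts adjusted over the list alone, median −0.20, camera adjusted p = 0.0344, adjusted p = 0.211 with an estimated correlation). AGO2, the slicing Argonaute, fell by 0.82 and DICER1 by 0.66. Both had risen with control siRNA (0.72 and 0.52), and after EZH2 siRNA neither differed from untransfected cells by the test (−0.11 and −0.14). TNFAIP3 had risen by 1.59 and stayed above untransfected cells (0.95).

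No rise against control siRNA was detected among the tested members of 2 lists of genes that Polycomb is known to silence. The lists hold 67 developmental regulators and 30 cancer genes, of which 36 and 15 were tested. The tested members had passed the background filter. Their lack of a detected rise therefore says little about members that stayed below it, and release of those was not tested here. None of 36 tested HOX and other developmental regulators was called (0 adjusted over the list alone, median −0.02, camera adjusted p = 0.752; fry, adjusted p = 0.55 for a common direction and 0.0209 for changes in either direction). Against untransfected cells 5 of the 36 rose and 0 fell with control siRNA (HOXB5, HOXB8, HOXD1, MSX1 and PAX8; camera adjusted p = 0.199). With EZH2 siRNA 5 rose and 0 fell too (HOXB6, HOXB8, HOXD1, MSX1 and PAX8; camera adjusted p = 0.416), all named after their values were seen. Between EZH2 siRNA and control siRNA in limma 3255 of all 17297 probes had an unadjusted p under 0.05. Of 15 tested cancer genes named as EZH2 targets, 2 fell and 0 rose (2 and 0 adjusted over the list alone, median −0.12, camera adjusted p = 0.261). IGFBP3, an IGF binding protein, fell by 0.71 and the Wnt antagonist DKK1 by 0.45. EZH2 itself was the 1 called gene of 10 PRC2 subunits (2 fell adjusted over the list alone, median −0.10, camera adjusted p = 0.148).

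The other lists were not called by camera. In each of the following lists 1 gene was called. S phase and G1/S (31 tested, median −0.09) had ORC6 of the origin recognition complex at −0.72 (−0.83 to −0.34 over the alternatives). The ORC6 call was lost with the mean over its probes. The p53 targets (17 tested, median −0.04) had the apoptosis effector BAX at 0.73. Epithelial genes (14 tested, median 0.13) had the claudin CLDN7 at 0.44. Mesenchymal genes (19 tested, median −0.07) had the receptor kinase AXL at −0.73. Immediate early genes (16 tested, median −0.02) had the phosphatase DUSP6 at −0.78, and histone genes (10 tested, median 0.03) had H2AC20 at 0.44. DUSP6 and ORC6 had risen with control siRNA (0.65 and 0.45) and did not differ from untransfected cells by the test after EZH2 siRNA (−0.13 and −0.28). CLDN7 was above background on 3 of the 4 control arrays. Of 17 genes of cholesterol and sterol synthesis, 1 rose and 2 fell (median −0.19), HSD17B7 at −0.79 and IDI1, above background on 2 of the 4 EZH2 siRNA arrays, at −0.75 (−1.35 to −0.39 over the alternatives). Of 25 hypoxia genes 1 rose, DDIT4, and 1 fell, ADM (median −0.01). Ribosomal proteins had 0 calls among 27 (median 0.01) and housekeeping genes 1 among 17 (median −0.07): HPRT1, a purine salvage enzyme often used as a reference gene, fell by 1.23. Markers of endothelial cells, fibroblasts and leukocytes were mostly below background, with 4, 3 and 3 tested genes and 0 called. Adjusted over the list alone, the counts of genes that rose and fell were 0 and 1 for S phase, 1 and 2 for p53 targets, 1 and 0 for epithelial genes, 1 and 2 for mesenchymal genes, 2 and 2 for immediate early genes and 2 and 0 for histone genes. They were 2 and 3 for cholesterol synthesis, 1 and 1 for hypoxia, 0 and 1 for housekeeping genes, 0 and 1 for fibroblast markers, and 0 for the ribosomal, endothelial and leukocyte lists. Of the 38 called genes named for this comparison besides EZH2, 14 lost the call without the 3 dimmest arrays: ANLN, AXL, BAX, BST2, CLDN7, DKK1, H2AC20, HSD17B7, IER3, IGFBP3, LAMB1, ORC6, PRC1 and TNFAIP3. Of these, ANLN, BAX, BST2, CLDN7, DKK1, H2AC20 and PRC1 lost it also when single arrays were left out (adjusted p up to 0.19). The fit without the dimmest arrays also has fewer arrays, so a call lost there need not mean a smaller change. Under the 75th percentile scaling 17 of the 38 lost the call, among them EMC6, NOLC1 and DDIT4, and 16 did with that scaling over the probes above background on all arrays. The latter scaling also lost the call of EZH2. With array brightness as a covariate ANLN, BAX, CLDN7, H2AC20, LAMB1 and PRC1 lost the call (6 of the 38).

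**Figure D4:**
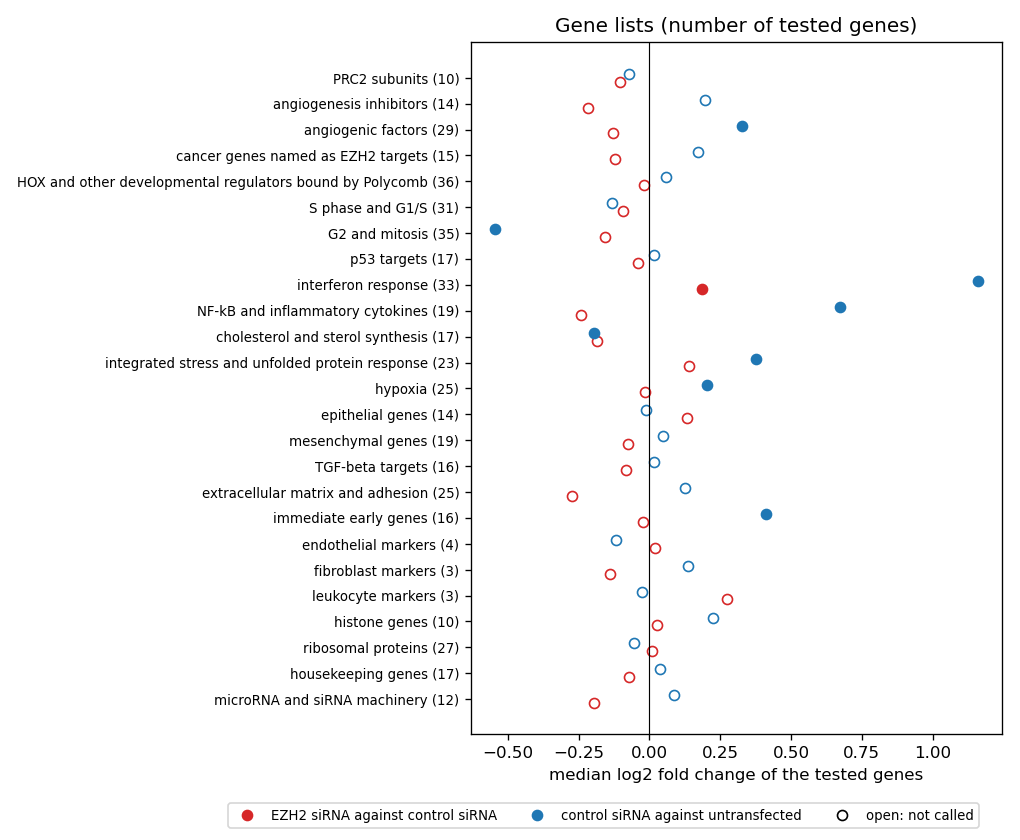
Median log2 fold change of the tested genes of each of the 25 lists (number of tested genes in brackets), for EZH2 siRNA against control siRNA (red) and control siRNA against untransfected cells (blue); filled points were called by camera with an estimated correlation. Interferon response has the highest median in blue, 1.16, and is the 1 filled red point at 0.18; the red median of the stress response changes sign under the 75th percentile scaling, and those of angiogenic factors and TGF-beta targets under that scaling over the probes above background on all arrays.

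Control siRNA against untransfected cells shows what transfection with a scrambled siRNA did. Interferon response genes changed the most. Of these, 31 of 33 tested members rose and 0 fell (32 and 0 adjusted over the list alone, median 1.16, adjusted p = 6.11e-06 with an estimated correlation). The antiviral GTPase MX1 rose by 4.53 on the log2 scale (23.1-fold, SE 0.13, adjusted p = 4.67e-15), IFI27 by 4.01 and IFI6 by 3.82. The transcription factor IRF9 rose by 3.06 and ISG15 by 3.04. OAS2, an RNA-sensing synthetase above background on 0 of 4 untransfected arrays, was at least 7.79-fold higher. NF-kB and inflammatory genes rose too, 15 of 19 with 0 falling (15 and 0 adjusted over the list alone, median 0.67, adjusted p = 0.00401 with an estimated correlation). They included CXCL8, a neutrophil-attracting chemokine (2.23), and IL1A (1.92).

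Genes of cell division went the other way in the control siRNA cells. Of 35 genes of G2 and mitosis, 19 fell and 0 rose (28 and 0 adjusted over the list alone, median −0.55, adjusted p = 0.000647 with an estimated correlation). The spindle gene KIF20A fell by 0.98 and TPX2 by 0.96. Of 31 genes of S phase and G1/S, 2 fell, RRM2 (−0.76) and POLE2 (−0.60), and 1 rose (4 and 2 adjusted over the list alone, median −0.13, camera adjusted p = 0.0122, adjusted p = 0.240 with an estimated correlation). Angiogenic factors rose, 11 of 29 with 1 falling (13 and 1 adjusted over the list alone, median 0.33, adjusted p = 0.00558 with an estimated correlation). Among them were the cytokine IL6 (1.65) and the lipoprotein lipase inhibitor ANGPTL4 (1.49). Of 14 angiogenesis inhibitors, the receptor kinase antagonist SPRY2 (0.70) and TIMP1 (0.52, named after its value was seen) rose and THBS1 fell by 0.87 (3 rose and 1 fell adjusted over the list alone, median 0.20, camera adjusted p = 0.0329, adjusted p = 0.310 with an estimated correlation).

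Stress and signalling genes also rose with control siRNA. The stress response had 9 of 23 genes higher and 0 lower (13 and 1 adjusted over the list alone, median 0.38, adjusted p = 0.0209 with an estimated correlation). They included PPP1R15A (1.90), a phosphatase subunit that restores translation, and DDIT4 (1.51). Immediate early genes had 7 of 16 higher and 1 lower (8 and 1 adjusted over the list alone, median 0.41, adjusted p = 0.00558 with an estimated correlation). They included DUSP5 (1.63) and the mRNA decay factor ZFP36 (1.29). Of 25 hypoxia genes 7 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.20, adjusted p = 0.0210 with an estimated correlation). Of 17 genes of cholesterol and sterol synthesis, ACAT2 fell by 0.54 and IDI1 fell by 0.45 (the same counts adjusted over the list alone, median −0.20, adjusted p = 0.0458 with an estimated correlation). Of 10 histone genes, H2AC18 (0.61) and H2BC12 (0.58) rose (the same counts adjusted over the list alone, median 0.22, camera adjusted p = 0.00901, adjusted p = 0.240 with an estimated correlation). The largest falls included TPM4 (−1.58), the endothelial proteoglycan ESM1 (−1.53), IGFBP3 (−1.52), the cytochrome P450 CYP1B1 (−1.46) and the protease PRSS23 (−1.44). CYP1B1 and PRSS23 were higher again with EZH2 siRNA than with control siRNA, by 1.0 and 0.80.

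The comparison of control siRNA with untransfected cells called 1128 probes, 673 higher and 455 lower, for 920 genes. Of 107 changes of at least 2-fold, 82 were upward. The arrays of the groups did not overlap for 94.7% of the calls. Camera called 11 lists at the preset correlation and 8 with an estimated one. The count of probes was 310 under a 75th percentile scaling (252 higher and 58 lower), 349 with that scaling over the probes above background on all arrays, and 704, 710 and 681 without control arrays 1, 3 and 4. The calls of ACAT2, H2AC18, H2BC12, IDI1 and POLE2 were lost when single arrays were left out (adjusted p up to 0.132). For lists at the preset correlation 3 of 35 splits of the 8 arrays called as many, the real one included. Splits that hold most arrays of a group together keep a part of its difference, so this count does not decide on chance.

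EZH2 siRNA against untransfected cells combines both steps. Interferon genes were again highest, with 31 of 33 higher and 0 lower (31 and 0 adjusted over the list alone, median 1.38, adjusted p = 1.46e-05 with an estimated correlation). MX1 rose by 4.85, IFI27 by 4.63 and IFI6 by 4.16. ISG15 rose by 4.05 and IRF9 by 3.04, and OAS2 was at least 9.02-fold higher. The largest falls were PRDX6 (−2.74), IGFBP3 (−2.23), ESM1 (−2.00), the tight junction gene CLDN11 (−2.00), THBS1 (−1.95) and MTPN (−1.62). Genes of G2 and mitosis fell in 27 of 35 cases and rose in 0 (32 and 0 adjusted over the list alone, median −0.74, adjusted p = 0.0009 with an estimated correlation). ANLN was at −1.34 and KIF20A at −1.11. The stress response had 15 of 23 genes higher and 0 lower (17 and 0 adjusted over the list alone, median 0.39, adjusted p = 0.0181 with an estimated correlation). DDIT4 was at 2.50 and PPP1R15A at 1.90.

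NF-kB genes stayed above untransfected cells in 14 of 19 cases, with 0 lower (15 and 0 adjusted over the list alone, median 0.74, adjusted p = 0.0215 with an estimated correlation). CXCL8 was at 1.76 and IL1A at 1.37. Immediate early genes had 9 of 16 higher and 1 lower (10 and 1 adjusted over the list alone, median 0.57, adjusted p = 0.0224 with an estimated correlation). DUSP5 was at 1.54 and ATF3 at 1.32. Cholesterol synthesis had 6 of 17 lower and 1 higher (8 and 2 adjusted over the list alone, median −0.30, adjusted p = 0.0442 with an estimated correlation). IDI1, above background on 2 of the 4 EZH2 siRNA arrays, was at −1.21 (−1.98 to −1.0 over the alternatives) and SQLE at −0.77. Another 5 lists were called at the preset correlation alone. Angiogenic factors had 10 of 29 genes higher, ANGPTL4 at 1.53 among them, and 3 lower (12 and 3 adjusted over the list alone, adjusted p = 0.118 with an estimated correlation). S phase had 6 of 31 lower, including RRM2 at −1.08 and TYMS at −0.65, and 1 higher (7 and 1 adjusted over the list alone, adjusted p = 0.139 with an estimated correlation). Hypoxia had 7 of 25 higher, including NDRG1 at 1.64, and 1 lower (the same adjusted over the list alone, adjusted p = 0.139 with an estimated correlation). TGF-beta targets had 6 of 16 lower, including THBS1 and CCN2 (−1.02), and 1 higher (the same adjusted over the list alone, adjusted p = 0.202 with an estimated correlation). Histone genes had 4 of 10 higher, including H2AC18 at 0.87 and H2AC20 at 0.74, and 0 lower (6 and 0 adjusted over the list alone, adjusted p = 0.191 with an estimated correlation). The angiogenesis inhibitors were not called here (3 of 14 higher and 2 lower, the same adjusted over the list alone); their median of 0.13 and their mean of −0.10 differ in sign.

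In total 2943 probes were called against untransfected cells, 1531 higher and 1412 lower, for 2288 genes. At least 2-fold were 101 and 92 of them. Of the 733 probes called against control siRNA, 430 were called in the same direction against untransfected cells, 178 higher and 252 lower. Independent lists would share 62.0, a number that leaves out that the comparisons share the EZH2 siRNA arrays. With these arrays halved, so that no EZH2 siRNA array stood in both comparisons, 108 to 200 probes were called in the same direction in the 6 halvings, where independent lists would share 10.4 to 55.7. The fold changes of both comparisons correlated at 0.61 across probes, against 0.50 in simulations in which the shared EZH2 siRNA arrays alone link them. With the EZH2 siRNA arrays halved in the same way, which removes that link, the correlation was 0.28 to 0.47. Probes are not independent replicates. The count against untransfected cells was 486 under a 75th percentile scaling (178 higher and 308 lower), 810 with that scaling over the probes above background on all arrays, 1132 without the 3 dimmest arrays and 1930 without EZH2 siRNA array 1.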

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

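The following tests were chosen only after the result was seen: the brightness covariate and the fit without dim arrays, the tests of the effect of the scrambled siRNA on raised genes, the halved covariance, and the interferon tests against brightness and against a stronger transfection response. The splits of the arrays, the test of brightness slopes and the test of the lowered genes were fixed before their results were seen.

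In the comparison of EZH2 siRNA with control siRNA, 733 probes were called, and the EZH2 siRNA arrays were dimmer by 0.37 on the log2 scale of the 75th percentile of raw signal. Chance placement of arrays is argued against for the count, since 1 of 35 splits of the 8 arrays, the real one, gave as many. The highest other split gave 0. A share of 1 in 35 is the smallest that this test can give. Other splits mix the groups, so a real difference widens their spread and lowers their counts. Chance between cultures is not covered if the arrays of a group repeat 1 culture. For the 9 lists called at the preset correlation 1 of 35 splits gave as many too, but the highest other split gave 8. That split placed control arrays 1, 3 and 4 with EZH2 siRNA array 3, which keeps a part of the group difference. The narrow margin therefore does not decide for or against chance. Of the single lists 1, interferon, was called with an estimated correlation. In the fit with brightness as a covariate 353 of the 733 probes stayed called, which argues against a linear effect of brightness as the whole cause. The other 380 lost the call, with a median absolute log2 fold change of 0.55 before and 0.44 after. Their median SE was 0.135 before and 0.150 after, and 101 others were called. A non-linear effect of brightness was not tested. A part of the calls may still follow brightness: slopes on brightness within the untransfected arrays predicted the called changes with a correlation of 0.033 across probes, but leaving out single untransfected arrays gave −0.16 to 0.24, which passes the bound of 0.2 set for excluding it, and brightness and group cannot be told apart further with 4 arrays each. Loss of EZH2 stays open as the biological explanation, as does an effect of the EZH2 siRNA on other mRNAs, which was not tested because the siRNA sequences are not given in the sources used here.

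The largest rises with EZH2 siRNA against control siRNA, such as TPM4, HABP4 and NOLC1, were in genes that the control siRNA had lowered. For rises of at least 2-fold, defined against 1 pair of control arrays and measured in the other pair, 67.4% of the rise lay below untransfected cells at the median of 6 halvings (62.7% to 92.6%, 9 to 18 probes), so these rises may reflect an effect of the scrambled siRNA rather than of EZH2. Over the 318 probes that rose most against 1 pair of control arrays, chosen anew in each halving, the share was 13.7% (−3.1% to 28.8%), and over the 415 that fell most 11.8% (2.57% to 25.6%); as these ranges reach past the bound of 20% set for excluding the scrambled siRNA, its part in the wider set of changes stays open. Whether control arrays shared by both comparisons account for the wider inverse relation stays open. With the control arrays halved the covariance ranged from −0.00953 to 0.00687 over 6 halvings, on both sides of 0, against −0.00807 with all of them. Simulations in which the shared control arrays alone link the comparisons gave −0.00959, so sharing alone can give a covariance of that size. A biological reading in which EZH2 siRNA raises these genes above the level of untransfected cells is available for OGFR and EMC6. They also rose against untransfected cells by 0.90 and 0.49. EMC6 is the less certain of them, with an exact permutation p of 0.0571 against untransfected cells. Its call against control siRNA was lost under the 75th percentile scaling (limma adjusted p = 0.104).

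Interferon genes were higher with EZH2 siRNA than with control siRNA, with a list median of 0.18. A linear effect of array brightness is argued against. With brightness as a covariate the median was 0.233 and the list stayed called at the preset correlation. A stronger response to transfection as a whole stays open: of the 7 other lists called with control siRNA with an estimated correlation, the medians of 4 went the other way here (NF-kB at −0.24 among them) and those of 3 went on in the same direction, and with an estimated correlation 0 of the 7 were called here. Chance could not be excluded for the size of the median, because 2 of 35 splits gave one as far from 0 (real 0.185, highest other 0.194). A difference in how strongly each siRNA itself sets off the interferon response, and loss of EZH2, may each account for the remaining difference and were not tested against each other; the list median ranged from 0.059 to 0.40 over the alternatives.

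For the other comparisons, chance placement of arrays is argued against for the counts of probes, within the same limits. With control siRNA against untransfected cells 1 of 35 splits gave as many as 1128 (highest other 0). With EZH2 siRNA against untransfected cells 1 of 35 splits gave as many as 2943 (highest other 275). The split with 275 joined untransfected arrays 1 and 2 with EZH2 siRNA arrays 2 and 3 (mean raw signal 282.7 to 409.8). The other arrays of these groups had 156.7 to 297.8, so this split nearly parts bright arrays from dim ones. Whether brightness gave its 275 calls was not tested. With brightness as a covariate 2413 of the 2943 probes stayed called. The splits do not settle whether chance can give the counts of called lists of these comparisons at the preset correlation. As many as 11 lists were given by 3 of 35 splits with control siRNA (highest other 12). With EZH2 siRNA 2 of 35 splits gave as many (highest other 11). Both of these highest splits placed 3 untransfected arrays with 1 transfected array, which keeps a part of the group difference. Splits that joined 2 arrays of each group called at most 2 and 5 lists in these comparisons.

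Single arrays lay far from the other 3 of their group for 8 of 172 combinations of a named gene and a group, where chance gives about 8.6 (1 in 20). On the log2 scale NEU1 was 8.02 on control siRNA array 2 against 8.18 to 8.20 on the others. MX1 was 7.19 on untransfected array 4 against 6.77 to 6.82. ISG15 was 7.58 on untransfected array 1 against 7.83 to 7.87. PRSS23 was 8.35 on untransfected array 3 against 8.74 to 8.80, and POLE2 was 8.56 on the same array against 8.95 to 9.01. PCK2 was 9.52 on EZH2 siRNA array 4 against 9.21 to 9.24. ANGPTL4 was 8.39 on control siRNA array 2 against 8.85 to 8.92. H2AC18 was 7.88 on control siRNA array 1 against 7.45 to 7.50.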

How the results depend on the processing

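Chosen only after the results were seen were the brightness covariate, the fit without the 3 dim arrays, the own-background correction and the 75th percentile shift over probes above background on all arrays. Of 97 called values of named genes, which leave out EZH2 against control siRNA, none changed sign in any alternative. This says little, because the genes were named for being called on these same arrays. With EZH2 siRNA against control siRNA 17 of 38 kept their call throughout; 21 of 30 did with control siRNA against untransfected cells and 28 of 29 with EZH2 siRNA against untransfected cells. The interferon list kept its direction and its call against control siRNA in every alternative. Camera with an estimated correlation (adjusted p = 0.0427) and fry were run on the main fit alone. All other alternatives used camera at the preset correlation. EZH2 kept its call when any 1 array was left out (−0.97 to −0.81); VASH1 was never called (0.039 to 0.127), and SUZ12, never called, ranged from −0.00294 (without EZH2 siRNA array 2) to 0.303.

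In the order EZH2 siRNA against control siRNA, control siRNA against untransfected, EZH2 siRNA against untransfected, and the overlap of both EZH2 siRNA comparisons, the counts moved as follows. The 75th percentile shift gave 144, 310, 486 and 64, with 6.25% of the first higher; VASH1 turned to −0.0547, SUZ12 to −0.202 and the stress list to −0.135, where the median of all probes was −0.106. Over the probes above background on all arrays it gave 98, 349, 810 and 52; EZH2 at −0.588 lost its call, and the lists of angiogenic factors (0.0508) and TGF-beta targets (0.0520) turned, where the median of all probes was 0.236. For both shifts the cause was not tested beyond that median. Array weights gave 1284 and 1867 for the first pair and an overlap of 662, and the own-background correction gave 433 for the first and 251 for the overlap; the cause was not tested. By construction, adjusted p under 0.01 gave fewer, 237, 528, 1330 and 125 (32.9% of the first higher), as did a log2 fold change of at least 1, 44, 107, 193 and 22 (27.3%). The brightness covariate gave 454 for the first, VASH1 turned to −0.00778, and G2 and mitosis (adjusted p = 0.136) and 6 of the 38 named genes lost their calls; the cause was not tested. Without the 3 dim arrays the counts were 169 for the first and 1132 for the third, with an overlap of 88, and SUZ12 was −0.0175. Fewer arrays and the loss of the dim ones cannot be told apart as the cause.

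Leaving out 1 array gave 278 to 1289 for EZH2 siRNA against control siRNA: 278 and 375 without EZH2 siRNA arrays 1 and 4, 298, 315 and 376 without control arrays 2, 3 and 4, and 1289 without EZH2 siRNA array 3. Control siRNA against untransfected gave 681 to 1194, with 704, 710 and 681 without control arrays 1, 3 and 4. EZH2 siRNA against untransfected gave 1930 (without EZH2 siRNA array 1) to 3213. The overlap was 165 to 783: 165, 783 and 217 without EZH2 siRNA arrays 1, 3 and 4, and 189, 199 and 237 without control arrays 2, 3 and 4. The share of higher calls was 33.6% to 49.7%. Camera calls were lost for the NF-kB list without control array 2 (adjusted p = 0.0546) or EZH2 siRNA array 2 (0.162), TGF-beta targets without EZH2 siRNA array 2 (0.149), G2 and mitosis without EZH2 siRNA arrays 3 (0.0619) and 4 (0.0589), and the microRNA and siRNA machinery without control arrays 1 (0.0668) and 2 (0.0575) and EZH2 siRNA arrays 2 (0.149) and 3 (0.0619). Apart from single arrays, the NF-kB list was not called with the mean over a gene's probes or by fry (adjusted p = 0.0552). The microRNA and siRNA machinery was not called with that mean or with the own-background correction.

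Over all groups, replicate numbers showed no pairing of the arrays (12 pairs of residuals with a median correlation of −0.013, 5 over 0.1). Between control and EZH2 siRNA arrays the same-number correlations were 0.241, 0.134, 0.218 and −0.116. Those of different numbers ranged from −0.366 to 0.239, so pairing is not excluded for this comparison. With the number as a block, 767, 1065 and 2924 probes were called and 459 overlapped, and H2AC20 and IDI1 lost 1 call each. A slide block was not run, as the files name no slide, and the planned offset of 50 is the main setting. Signal over background limits what can be tested: 31506 of 48803 probes were not tested.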

Other observations

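The set of genes changed in both steps, and the genes named from it, were chosen only after the result was seen, whereas the test of silent genes was fixed before.

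Some genes moved the same way in both steps, from untransfected to control siRNA and again from control siRNA to EZH2 siRNA. There were 43 such probes, 22 higher and 21 lower, where independent lists would share 23.3. More probes were called in opposite directions, 93 (52 higher and 41 lower in the second step), where independent lists would share 24.5; the shared control arrays favour such pairs. Interferon genes not described above were among the higher ones: IFIT1 rose by 1.80 and then 0.51, IFI35 by 1.63 and 0.59, IRF7 by 1.57 and 0.50, and the ISG15-conjugating enzyme UBE2L6 by 1.19 and 0.52. The stress transcription factor DDIT3 rose by 1.03 and 0.55 and the pseudokinase TRIB3, one of its targets, by 0.63 and 0.51. The lower ones included CYP24A1, the vitamin D hydroxylase, at −1.02 and −0.59, the spindle protein FAM83D at −0.73 and −0.68, the actin-binding protein PALLD at −0.47 and −0.93, and the E2F partner TFDP1 at −0.39 and −0.91. THBS1, at −0.87 and −1.08, was the 1 gene of the angiogenesis inhibitors in this set. Both steps share the control arrays, which links their errors in opposite directions, so the sharing does not raise the count of same-direction probes.

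Loss of a silencing enzyme might bring up genes that were silent before. Probes above background on 0 of 4 control arrays and on 4 of 4 EZH2 siRNA arrays numbered 2 (C1orf210 and GNPTAB, named after their values were seen), and the reverse change was seen for 96, a difference of −94. The condition set in advance for excluding the idea, no more gained than lost, was wrong, because the EZH2 siRNA arrays were dimmer (31.2% against 35.4% of probes above background), which takes dim probes below background whatever EZH2 does; 69 of 70 ordered splits of the arrays had a difference as large or larger, with up to 117. Release of silent genes therefore stays open.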
